A study of Mus musculus with 12 samples.

How the data were processed

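Gene expression was measured by RNA sequencing in 12 libraries labelled as sorted mouse cortical neurons, 3 in each of 4 groups. The groups were adult control, P4, stroke, and stroke with GDF10 siRNA. Per the labels, total RNA was isolated with the RNA-Microprep kit, amplified with the Ovation RNA-seq System v2 and sequenced as paired 69 bp reads. The labels do not say what P4 stands for, at what time after stroke the tissue was taken, or whether the replicates of a group were separate animals. The authors' processing notes name CASAVA 1.8.2, edgeR and the mouse genome build mm10. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here.

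The deposited table held 23253 genes by symbol. Its raw read counts, in counts per gene and library, were the values analysed here. The authors' normalized counts, a signal rescaled by the authors, were not used in any test. The deposited table also gave the authors' log2 fold changes, and their p-values and false discovery rates, for each pair of groups. These were compared with the tests made here for 5 pairs. The siRNA group against P4, and 18 columns of log ratios per library, were not analysed here. The column of the first P4 library is named P3 in the table and was matched to its sample by its replicate number. The comparison columns name the siRNA group only as stroke with GDF10, and the sample labels name the siRNA.

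Gene positions were taken from the RefSeq annotation of the same genome build. Genes were matched by Entrez gene ID, or by symbol where the ID gave no match, and 22921 genes were matched. Of 18965 genes with a chromosome in both sources, 18948 had the same one. Reads of close paralogs cannot be assigned with certainty without the settings of the aligner. This applies here to C4b, the Serpina3 and H2 families, Hspa1b and Tubb2b. Reads counted for Mir6390 cannot be told from reads of a longer transcript over the same position.

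Counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr by group, which left 17909 genes. Libraries were scaled with TMM factors, and all 12 libraries were fitted together with 1 mean per group by the quasi-likelihood method of edgeR 4.0.16. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over the 3 libraries of a group, with n = 3 throughout. Fold changes are on the log2 scale, with an approximate standard error (SE) where given. This SE is the absolute log2 fold change divided by the square root of the F value of its test. The 5 comparisons were stroke against adult control, siRNA-labelled stroke against stroke, P4 against adult control, siRNA-labelled stroke against adult control, and stroke against P4.

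Before the data were examined, 45 gene lists were fixed: 16 of cell type markers, 4 of quality measures and 25 of pathways. The 42 lists with at least 5 tested genes were tested with camera in limma 3.58.1. The test used log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p was adjusted over the lists of a comparison. Each list test was repeated with a correlation estimated from the data. Members of a list were also adjusted over the list alone. Marker shares are the percent of all counts that fell on a list's genes.

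The rule for named genes was also fixed before the data were examined. It took Gdf10, the 8 genes with the largest change in each direction, and the 2 members with the smallest p in each list that passed or held at least 2 called genes. The largest changes were taken among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, without predicted genes. Where fewer than 5 genes met this in a direction, the 5 with the smallest p were taken. In the last 2 comparisons the rule took 4 genes per direction and no list members. In the comparison of P4 with adult control the rule named over 100 genes, and the text gives part of them. Bmp4 in the stroke comparison, H2-K1 and Slc1a3, the list members named in the comparison of the siRNA-labelled group with adult control, and Tuba1a were named after their values were seen. Where a group had 0 counts, a fold is a lower bound against 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% binomial interval. Such intervals cover counting error only, because reads from amplified cDNA are not independent molecules.

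Total counts ranged from 10517638 to 48633350 per library. The test was tried on simulated counts with the depths and the spread of these libraries. In the simulated stroke comparison it recovered 0 of 50 genes changed by 1 on the log2 scale, 8 of 50 changed by 2, 24 of 49 changed by 3 and 40 of 50 changed by 5, with 4 false calls among 16908 genes. In the simulated siRNA comparison it recovered 0 of 50, 7 of 50, 27 of 50 and 36 of 49, with 5 false calls among 16878 genes.

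For effects that share a group, counts were simulated for unchanged groups that share the same libraries, 20 times each, because a shared group alone gives a correlation. For the percent of opposite signs, separate simulations kept the observed effect of stroke. They set only P4 equal to adult control, or the siRNA-labelled group equal to stroke, and took the genes called in each simulation. All these simulations drew each gene on its own, without shifts that many genes of a library share. The following alternatives were planned: DESeq2 size factors (RLE) and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom, no filter on low counts, and a minimum of 1 CPM in 3 libraries. Also planned were fits of only the 2 groups compared, robust dispersions, an adjusted p under 0.1, a log2 fold change of at least 1, no 45S pre-rRNA gene, replicate number as a block in a fit of only the 2 groups, fry in place of camera, and fits without each library in turn. The following were added after the data were seen: library class as a term, the edgeR exact test on all genes, offsets for GC content and transcript length, and tests without Y-linked genes and Xist. Library class was defined from the data as counts of the 45S pre-rRNA gene entry above or below 1% of all counts.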

Results

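Per the labels, cortical neurons were sorted from C57BL/6 mice by flow cytometry, and RNA was sequenced in 12 libraries. Adult control, P4, stroke, and stroke with GDF10 siRNA had 3 libraries each. Adult control and siRNA-labelled libraries were numbered 1 to 3, and stroke and P4 libraries 4 to 6. A batch that follows these numbers could not be told from the group where stroke or P4 was set against adult control. The same holds for the siRNA-labelled group against stroke. Stroke was induced by illuminating the cortex with cold light for 15 min after rose bengal, a photosensitive dye, which gave a focal lesion of 2 mm. GDF10 is a secreted protein of the TGF-beta family, and the series asks what role it has in axonal sprouting and recovery after stroke. Total counts in adult control 1, 2 and 3 were 21821572, 36009796 and 10517638. In stroke 4, 5 and 6 they were 31525800, 30615708 and 18246470. In the siRNA-labelled libraries 1, 2 and 3 they were 16887717, 19276528 and 33082818, and in P4 4, 5 and 6 they were 48633350, 46028261 and 17544485.

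Gdf10 (chromosome 14, 33923587 to 33936514, mm10) was near the limit of detection in the adult groups. Its raw counts were 15, 21 and 0 in adult control, 0, 5 and 0 in stroke, 8, 7 and 1 in the siRNA-labelled libraries, and 189, 241 and 33 in P4. Its level was 0.372 ± 0.324 CPM in adult control, 0.0534 ± 0.0924 in stroke, 0.309 ± 0.247 in the siRNA-labelled group and 3.47 ± 1.34 in P4 (SD, n = 3 each). Gdf10 was thus not lower in the siRNA-labelled libraries than in stroke, with a log2 fold change of 2.34 (SE 1.67, adjusted p = 0.778). That value rests on the 5 counts of stroke 5. It was 1.76 without stroke 4 and 6.11 without stroke 5, which leaves 0 counts in stroke, and it passed in neither. A difference in Gdf10 between these groups was not detectable at this depth. The sample labels name this treatment as GDF10 siRNA, the deposited comparisons name it only as GDF10, and the counts do not settle which was given. It is called siRNA-labelled throughout for that reason.

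Oligodendrocyte markers took a larger share of counts than pan-neuronal markers in the 3 adult groups, although the libraries were labelled as sorted neurons. The 12 oligodendrocyte markers, genes of the myelin-forming glia, took 5.87 ± 3.09% of counts in adult control, 5.98 ± 0.64% in stroke, 9.04 ± 2.14% in the siRNA-labelled group and 0.0206 ± 0.0101% in P4 (SD, n = 3 each). The 15 pan-neuronal markers took 0.487 ± 0.231%, 0.2 ± 0.0278%, 0.255 ± 0.0673% and 1 ± 0.0814% in the same order. Microglia and macrophage markers, genes of the brain's immune cells, took 0.101 ± 0.0284% in adult control, 0.0893 ± 0.0649% in stroke and 0.299 ± 0.122% in the siRNA-labelled group. Oligodendrocyte precursor markers took 0.238 ± 0.146%, 0.429 ± 0.0796% and 0.222 ± 0.0604%, and astrocyte markers 0.492 ± 0.115%, 0.107 ± 0.0214% and 0.12 ± 0.033% in these 3 groups. The gene entry for the 45S precursor of ribosomal RNA took 2.44, 2.11 and 2.11% of counts in stroke. It took 0.427, 2.08 and 0.0964% in adult control and 0.329, 0.304 and 2.72% in the siRNA-labelled libraries. In P4 it took 0.142, 0.349 and 0.00984%. Xist, an RNA made from the inactive X chromosome of females, was at 2592 ± 916 CPM in P4 and at 67.6 ± 109 CPM in adult control. The latter mean rests on 193 CPM in adult control 3. Ddx3y, a Y-linked gene, was at 0.056, 33.5 and 148 CPM in P4 4, 5 and 6. Its level was 109 to 474 CPM in adult control and 116 to 160 CPM in stroke. The comparisons of P4 with these groups are thus not matched for sex markers. Adult control 3, the library with the fewest counts, stood apart from the others on the first 2 principal components. The correlation of log2 CPM between libraries of 1 group was between 0.681 and 0.989.

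**Figure D1:**
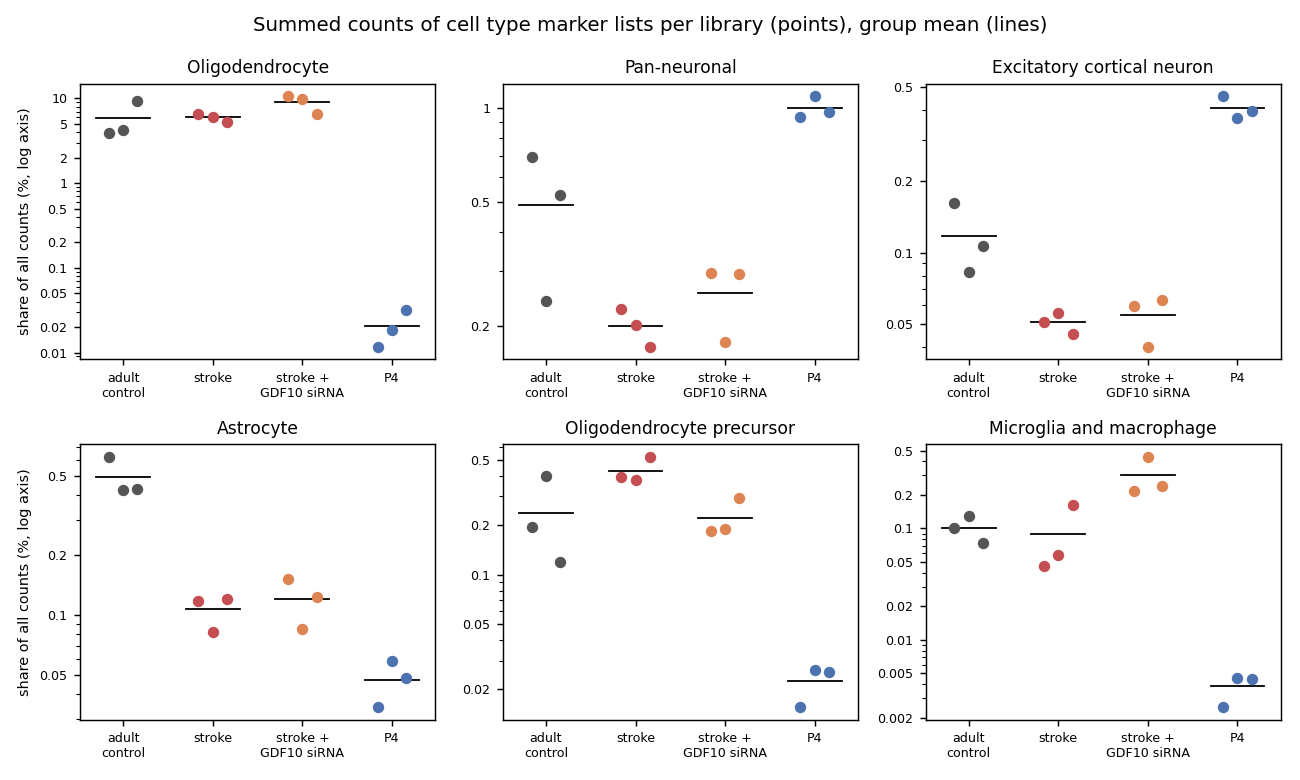
Share of all counts (percent, log axis) that fell on 6 sets of cell type markers in each library of the 4 groups (points), with the group mean (lines, n = 3). Oligodendrocyte markers took 5.87, 5.98 and 9.04% of counts in adult control, stroke and the siRNA-labelled group and 0.0206% in P4.

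The first comparison asked which genes differed between the stroke and adult control libraries. Interferon response genes, which cells switch on against viruses and after injury, were far higher in stroke than in adult control. Ifit1, an interferon-induced RNA-binding protein (chromosome 19, 34640889 to 34650009), rose from 0.587 ± 0.516 to 302 ± 78.5 CPM (log2 fold change 8.80, SE 0.76, adjusted p = 9.73e-05). Serpina3n, a protease inhibitor made by reactive astrocytes (chromosome 12, 104406646 to 104414334), rose from 15.5 ± 10.6 to 2881 ± 578 CPM (7.53, SE 0.66, adjusted p = 9.73e-05). Complement C4b (chromosome 17, 34728139 to 34743902) rose from 9.05 ± 3.59 to 805 ± 158 CPM (6.47, SE 0.67, adjusted p = 0.000415). Slc1a2, the main glutamate transporter of astrocytes (chromosome 2, 102658239 to 102790784), fell from 4122 ± 871 to 563 ± 153 CPM (-2.87, SE 0.37, adjusted p = 0.00219).

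Of the 26 interferon response genes, 14 rose in stroke and none fell, and 22 rose when adjusted over the list alone. Their median log2 fold change was 3.45 (camera adjusted p = 7.69e-29). Oasl2 rose by 6.66, and Usp18, which limits interferon signalling, by 6.57. Mx1, annotated as a transcribed pseudogene in this genome, rose by 6.30, and Rtp4 by 4.94. Of 24 complement and MHC class I genes, 3 rose (C4b, H2-D1 by 3.38 and H2-K1 by 2.28), and 8 when adjusted over the list alone (median 1.51, camera adjusted p = 1.07e-05, and adjusted p = 0.0993 with an estimated correlation). Spp1, or osteopontin, rose by 4.12, Cxcl10, a chemokine, by 4.91, and Gpnmb, a glycoprotein of activated phagocytes, by 5.12. The 16 microglia and macrophage markers did not pass as a list (median 0.28, camera adjusted p = 0.651).

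Growth cone and immature neuron genes, which are active in growing axons, were higher in stroke as a list. Their median was 1.03 over 28 genes (camera adjusted p = 4.55e-05). Tubb2b, a tubulin of young neurons, rose by 2.51 (SE 0.52, adjusted p = 0.0381), and Marcksl1, an actin regulator, by 2.76 (SE 0.55, adjusted p = 0.0345). Igfbpl1 had 191 counts in stroke and 3 in adult control, a ratio of 60.2 (95% interval 20.3 to 294). These 3 genes rose and none fell over all genes, and 10 rose and 1 fell when adjusted over the list alone. Gap43, a growth cone protein (chromosome 16, 42248552 to 42340651), was at 31.1 ± 15.3 CPM in stroke and 20.3 ± 7.83 CPM in adult control. Oligodendrocyte precursor markers, 0 of which passed over all genes, also lay higher as a list (median 1.08, camera adjusted p = 0.0203, and adjusted p = 0.513 with an estimated correlation). That call was lost without adult control 1 (adjusted p = 0.172) or stroke 6 (0.0505). Of 35 regeneration-associated genes, known from injured neurons that regrow axons, Csf1 rose by 2.46 and Tubb2b as above. Adjusted over the list alone, 8 rose and 1 fell (median 0.49, camera adjusted p = 0.0139, and adjusted p = 0.0993 with an estimated correlation). Of the 23 TGF-beta family ligands and antagonists, Bmp4, a growth factor, rose by 2.50 (adjusted p = 0.0208), the same 1 gene as adjusted over the list alone. None of the 20 TGF-beta and BMP receptors and SMADs and none of the 18 response genes passed, over all genes or adjusted over the list alone. The 3 TGF-beta lists had camera adjusted p of 0.651, 0.726 and 0.859.

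Markers of astrocytes and of excitatory neurons were lower as lists in stroke than in adult control. Of 12 astrocyte markers, 4 fell: Slc1a2, the glutamate transporter Slc1a3 by -2.10, and the gap junction genes Gjb6 by -4.73 and Gja1 by -4.42. Adjusted over the list alone 7 fell and 2 rose (median -2.04, camera adjusted p = 0.000706, and adjusted p = 0.0993 with an estimated correlation). The share of reactive astrocyte markers, a separate list that holds Serpina3n, went the other way. It was 0.0124 ± 0.00358% of counts in adult control, 0.297 ± 0.0611% in stroke and 0.0697 ± 0.0215% in the siRNA-labelled group. In stroke this share rests largely on Serpina3n, so it does not measure the list as a whole. The mean log2(CPM + 1) over the 12 members differed less. It was 1.98, 1.72 and 2.54 in adult control, 2.70, 2.70 and 3.42 in stroke, and 2.92, 4.15 and 2.67 in the siRNA-labelled libraries. Of 15 excitatory cortical neuron markers, 2 fell, among them the transcription factor Rorb (-3.09), and 7 when adjusted over the list alone (median -1.34, camera adjusted p = 0.000884, and adjusted p = 0.222 with an estimated correlation). None of 14 GABA receptor genes passed over all genes, and 5 were lower when adjusted over the list alone (median -1.03, camera adjusted p = 0.000884, and adjusted p = 0.318 with an estimated correlation). The potassium channel gene Kcnc2 fell by -2.92. Of 12 oligodendrocyte markers, Cldn11, a myelin tight junction protein, rose by 2.23, also when adjusted over the list alone (median 0.47, camera adjusted p = 0.0302, and adjusted p = 0.47 with an estimated correlation), and this list call was lost without adult control 1 (adjusted p = 0.169) or stroke 4 (0.139). Of 24 dissociation response genes, which rise when tissue is taken apart, Zfp36 (1.74) and Fos (1.86) rose and the heat shock gene Hspa1b fell (-2.78). Adjusted over the list alone 11 rose and 2 fell (median 1.07, camera adjusted p = 0.000154, and adjusted p = 0.222 with an estimated correlation). The largest falls were in Mir6390, with 0 counts in stroke and 458 in adult control, at least 162-fold lower, and in Tfr2 (-7.71), Ranbp3l (-7.23) and Svep1 (-5.65). Adult control 3 held most of the counts of 3 of these genes, and without it their calls were lost. Mir6390 was at 2.73, 0.89 and 40.1 CPM in adult controls 1, 2 and 3 (adjusted p = 0.167 without the last). Without that library the log2 fold change of Tfr2 was -4.50 (adjusted p = 0.0557) and that of Svep1 -3.41 (adjusted p = 0.215).

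In all, 126 of 17909 genes changed between stroke and adult control by the edgeR test, 87 higher and 39 lower, and 2852 had an unadjusted p under 0.05. The libraries of both groups did not overlap in any of the 126 genes, against 20% of all genes, and chance gives 10%. Of the 42 lists, 18 passed, and 2 of these, interferon response (adjusted p = 0.0126) and growth cone genes (adjusted p = 0.0177), held with an estimated correlation. More genes were lower than higher with the DESeq2 Wald test (438 higher, 976 lower), the edgeR exact test on all genes (183 and 223), the deposited table (269 and 433) and without adult control 2 (239 and 309). The count was 43 in a fit of only these 2 groups, 41 with library class as a term, 32 without adult control 1, 548 without adult control 2, and 35, 31 and 36 without stroke 4, 5 and 6. Of 36 called genes named by the fixed rule, 8 kept the call in every fit that left out 1 library, among them Ifit1, C4b, Slc1a2, Serpina3n, Cldn11, Oasl2 and Usp18.

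**Figure D2:**
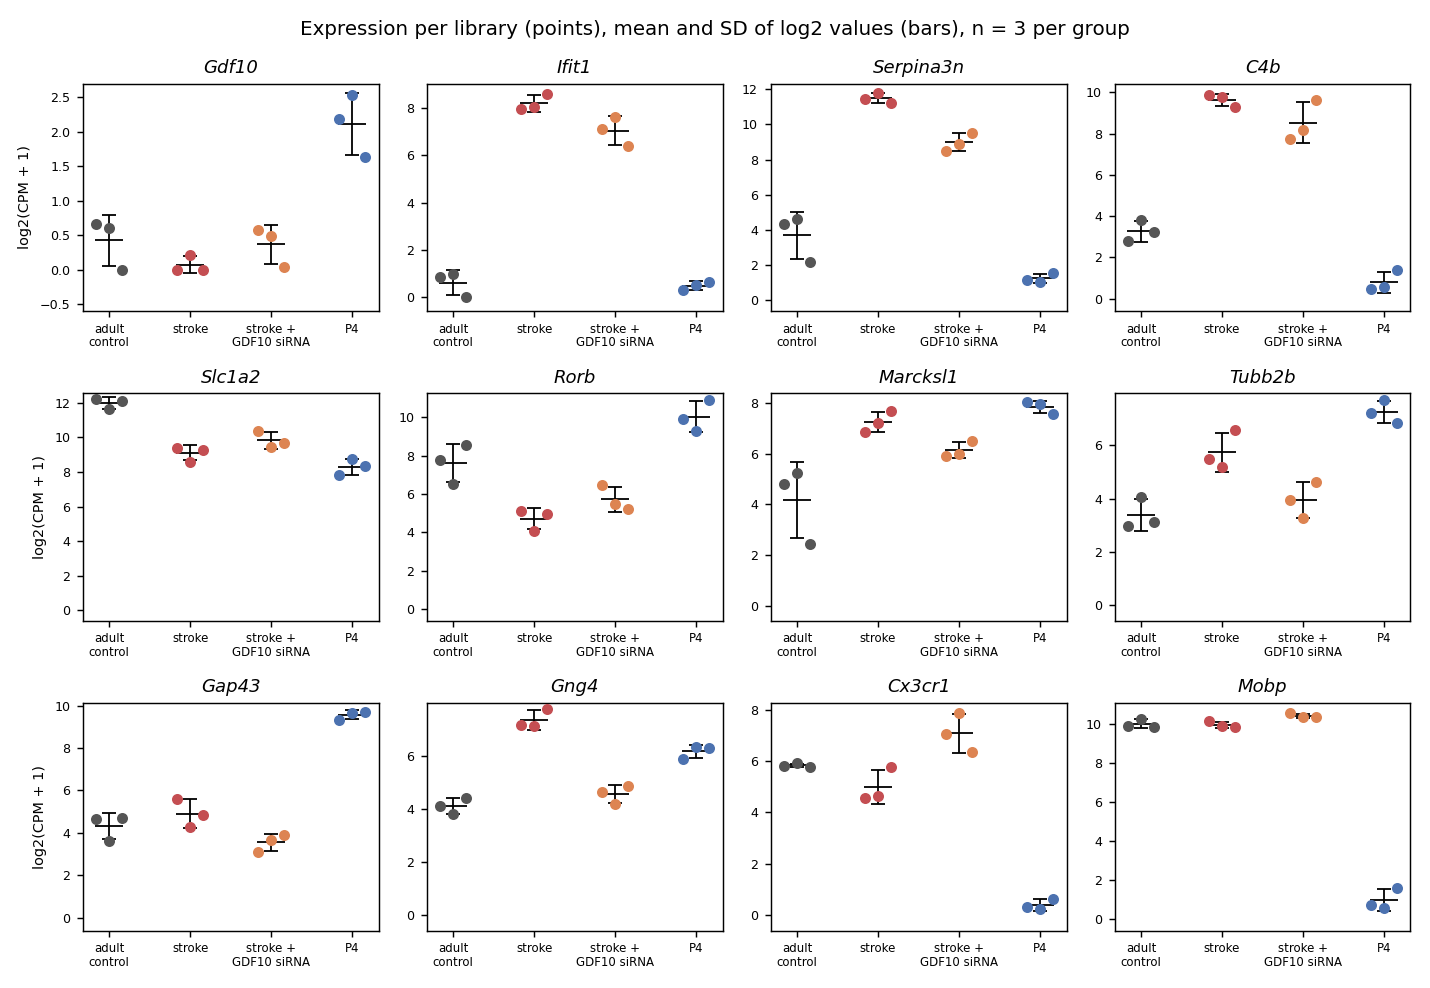
Levels of 12 genes as log2(CPM + 1) in each library of the 4 groups, with the group mean and SD (n = 3). Ifit1 was at 302 CPM in stroke and 0.587 CPM in adult control, and Gdf10 stayed under 1 CPM in every adult library.

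The second comparison asked what differed between the libraries labelled stroke with GDF10 siRNA and those labelled stroke. One gene changed over all 17909 tested. Gng4, a gamma subunit of G proteins (chromosome 13, 13784059 to 13827895), fell from 167 ± 45.5 CPM in stroke to 23.02 ± 5.37 CPM in the siRNA-labelled group (log2 fold change -2.85, SE 0.37, adjusted p = 0.023). It was at 16.5 ± 3.63 CPM in adult control and 71.6 ± 11.7 CPM in P4. Growth cone and immature neuron genes were lower as a list in the siRNA-labelled group than in stroke, with a median of -1.05 (camera adjusted p = 4.3e-08). None of the 28 passed over all genes, and 6 were lower when adjusted over the list alone. Gap43 was at 11.2 ± 3.17 CPM in the siRNA-labelled group (log2 fold change -1.48, adjusted p = 0.485). Tubb2b was at 15.6 ± 7.48 CPM, against 57.9 ± 32.1 CPM in stroke (-1.89, adjusted p = 0.466). The list was the 1 of 11 passing lists that held with an estimated correlation (adjusted p = 0.00558). Of the 11, 8 were lower, among them cytosolic ribosomal proteins, a quality list (median -0.262, and 0.267 with library class as a term). Tuba1a, the main alpha tubulin of young neurons, had a log2 fold change of -1.92 (adjusted p = 0.549).

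Microglial and inflammatory genes were higher as lists in the siRNA-labelled group than in stroke. The 16 microglia and macrophage markers had a median log2 fold change of 1.67 (camera adjusted p = 4.3e-08, and adjusted p = 0.31 with an estimated correlation). None passed over all genes, and 6 were higher when adjusted over the list alone. Cx3cr1, the fractalkine receptor of microglia (chromosome 9, 120048683 to 120068296), was at 148 ± 77.2 CPM against 33.3 ± 17.3 CPM in stroke (2.15, adjusted p = 0.445). Of 24 inflammatory cytokine and chemokine genes none passed, and 3 were higher when adjusted over the list alone (median 1.53, camera adjusted p = 4.45e-06, and adjusted p = 0.196 with an estimated correlation). Tnfaip3, a brake on NF-kappaB, had a log2 fold change of 2.46 (adjusted p = 0.394) and the chemokine Cxcl2 of 3.3 (adjusted p = 0.445). The smallest p among higher genes belonged to Lpl, a lipase (chromosome 8, 68880555 to 68906932), at 96.0 ± 93.4 against 2.27 ± 1.497 CPM (5.38, adjusted p = 0.275). Mertk, a receptor for engulfing dead cells, was at 87.1 ± 24.1 against 17.3 ± 2.72 CPM (2.33, adjusted p = 0.303). Cd83 (2.40), Itga6 (2.35) and Havcr2 (3.61) did not pass either. The 12 monocyte and neutrophil markers made up 0.018% of counts in adult control, 0.0458% in stroke and 0.114% in the siRNA-labelled group, where the libraries had 0.0448, 0.1497 and 0.1488%. Of the 7 tested, none passed over all genes or adjusted over the list alone, and the list did not pass (median 1.24, camera adjusted p = 0.05, and adjusted p = 0.428 with an estimated correlation). Mural cell markers, genes of vessel walls, passed as the other higher list (median 1.83, camera adjusted p = 0.000626, and adjusted p = 0.196 with an estimated correlation), with 0 of 9 genes passing over all genes or adjusted over the list alone. Their share was 0.00453% in adult control, 0.00105% in stroke and 0.00242% in the siRNA-labelled group, so few counts carry this list, and its median was 0.569 without siRNA-labelled library 1 and 0.854 with library class as a term. The mural cell marker Pdgfrb was at 3.38 ± 2.63 against 0.191 ± 0.19 CPM (4.09, adjusted p = 0.597). The mural cell list was lower in stroke than in adult control (median -3.04, camera adjusted p = 0.000179, and adjusted p = 0.0993 with an estimated correlation), a difference that shares the stroke libraries.

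Interferon response genes were lower as a list in the siRNA-labelled group than in stroke. None of the 26 passed over all genes, and 3 were lower when adjusted over the list alone (median -0.91, camera adjusted p = 4.45e-06, and adjusted p = 0.196 with an estimated correlation). Stat2, a transcription factor of the interferon response, had a log2 fold change of -1.40 (adjusted p = 0.445), and Ddx58, a sensor of viral RNA, of -1.58 (adjusted p = 0.445). None of the 10 oligodendrocyte precursor markers passed, over all genes or adjusted over the list alone (median -0.84, camera adjusted p = 0.000626, and adjusted p = 0.428 with an estimated correlation). Sox10, a transcription factor of this lineage, was at 386 ± 88.4 against 841 ± 143 CPM (-1.13, adjusted p = 0.594). The same held for the 14 inhibitory neuron markers, with 0 calls (median -1.20, camera adjusted p = 0.000626, and adjusted p = 0.182 with an estimated correlation). Of 35 regeneration-associated genes none passed, and 5 were lower and 1 higher when adjusted over the list alone (median -0.38, camera adjusted p = 0.0479, and adjusted p = 0.196 with an estimated correlation). That list did not pass without stroke 4 (adjusted p = 0.0812) or without siRNA-labelled libraries 1 (0.091) or 3 (0.0537). None of the genes of the 3 TGF-beta lists passed, over all genes or adjusted over the lists alone, and the lists had camera adjusted p of 0.758, 0.5 and 0.478. Among lower genes, Col20a1 (-3.16), Hsd17b7 (-1.94), an enzyme of cholesterol synthesis, Pik3r3 (-1.74), a regulatory subunit of PI3-kinase, and Frmd4a (-1.92) had adjusted p between 0.275 and 0.301.

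The edgeR test thus called 1 gene between the siRNA-labelled group and stroke, and 1319 genes had an unadjusted p under 0.05. The DESeq2 Wald test called 203 genes, limma voom 8, the exact test on all genes 13, and a fit of only these 2 groups 88 (45 higher, 43 lower). The count was 0, with Gng4 lost, with RLE or upper-quartile scaling, with library class as a term and with GC and length offsets. Without any 1 of the 6 libraries the count was 0, with 867 to 2188 genes at an unadjusted p under 0.05. In those fits Gng4 had an adjusted p of 0.104, 0.0841 and 0.23 without stroke 4, 5 and 6, and of 0.362, 0.373 and 0.0572 without siRNA-labelled libraries 1, 2 and 3. Its log2 fold change was between -3.03 and -2.61 in these 6 fits.

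The third comparison set P4 against adult control. Oligodendrocyte markers took 5.87% of counts in adult control and 0.0206% in P4, and pan-neuronal markers 0.487 and 1%. In comparisons with P4, a different mix of cells therefore cannot be told from changes within a cell type. Growth cone and immature neuron genes were far higher in P4. Dpysl3, which organizes the growth cone cytoskeleton (chromosome 18, 43320979 to 43438286), rose by 4.93 (SE 0.33, adjusted p = 1.27e-06). Gap43 rose from 20.3 ± 7.83 to 763 ± 104 CPM (5.23, adjusted p = 3.12e-06). Myelin genes were almost absent from P4. Mobp, a myelin protein (chromosome 9, 120149742 to 120181488), fell from 1042 ± 172 to 1.05 ± 0.853 CPM (-10.07, adjusted p = 7.8e-08). Gdf10 was at 3.47 ± 1.34 CPM in P4, with a log2 fold change of 3.15 that did not pass (adjusted p = 0.224), although it passed with limma voom (3.44, adjusted p = 0.0481).

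Of 28 growth cone and immature neuron genes, 24 rose in P4 and none fell, and 26 rose when adjusted over the list alone (median 3.56, camera adjusted p = 1.03e-17). Stmn2, a microtubule regulator, rose by 5.56, the transcription factor Sox11 by 3.97, the surface protein Cd24a by 8.02 and the axon guidance protein Draxin by 7.22. Igfbpl1 had 2628 counts in P4 and 3 in adult control, a ratio of 544 (95% interval 186 to 2640). Of 15 pan-neuronal markers 9 rose, and 10 when adjusted over the list alone (median 1.72, camera adjusted p = 6.17e-06, and adjusted p = 0.126 with an estimated correlation). Of 15 excitatory cortical neuron markers 9 rose, among them the glutamate transporter Slc17a6 (4.10), and Camk2a, a kinase of mature synapses, fell (-1.59). Adjusted over the list alone 11 rose and 1 fell (median 2.35, camera adjusted p = 2.86e-05, and adjusted p = 0.097 with an estimated correlation). The Camk2a call was lost without adult control 1 (adjusted p = 0.0816) and without P4 4 (0.0976) or 5 (0.0561). Of 35 regeneration-associated genes 10 rose and 6 fell, and 11 and 8 when adjusted over the list alone (median 0.56, camera adjusted p = 0.0335, and adjusted p = 0.097 with an estimated correlation). Syndig1l (7.57), Mdga1 (6.68), Prokr2 (6.60), the gap junction gene Gjc1 (6.59) and Lpl (6.57) were among the largest rises. The Syndig1l call was lost without adult control 1 (adjusted p = 0.0593) and without P4 4 (0.0504) or 5 (0.0519).

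Glial and immune markers were lower in P4. All 12 oligodendrocyte markers fell, also when adjusted over the list alone (median -8.66, camera adjusted p = 6.55e-20). Mal fell by -10.20, Ermn by -10.00 and Cldn11 by -8.60. All 10 oligodendrocyte precursor markers fell, also when adjusted over the list alone (median -3.96, camera adjusted p = 3.91e-09, and adjusted p = 0.097 with an estimated correlation). Of 16 microglia and macrophage markers 15 fell, and 16 when adjusted over the list alone (median -4.64, camera adjusted p = 2.82e-12, and adjusted p = 0.097 with an estimated correlation). Cx3cr1 fell by -7.53 and P2ry12, a receptor of resting microglia, by -7.57. Tmem119, a microglial membrane protein, had 2 counts in P4 and 2166 in adult control, a ratio of 1740 (95% interval 482 to 14400). Of 12 astrocyte markers 8 fell, and 9 when adjusted over the list alone, among them Slc1a2 (-3.67) and S100b (-4.87) (median -2.37, camera adjusted p = 1.92e-06). Of 24 complement and MHC class I genes 12 fell, and 16 when adjusted over the list alone (median -3.26, camera adjusted p = 1.46e-05, and adjusted p = 0.097 with an estimated correlation). Of 26 interferon response genes 6 fell, and 11 when adjusted over the list alone (median -1.15, camera adjusted p = 0.00383, and adjusted p = 0.309 with an estimated correlation). The interferon call was lost without adult control 2 (adjusted p = 0.0538). Of 24 dissociation response genes 16 fell, and 18 when adjusted over the list alone (median -2.25, camera adjusted p = 1.18e-09, and adjusted p = 0.0958 with an estimated correlation). Serpina3j had 0 counts in P4 and was at 0.36, 0.02 and 40.0 CPM in adult controls 1, 2 and 3, so its fold rests on the last of these. It lost its call without adult control 3 (adjusted p = 0.214) and without P4 4 (0.0972), 5 (0.0935) or 6 (0.0709).

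TGF-beta genes moved both ways in P4. Of 20 TGF-beta and BMP receptors and SMADs 2 rose and 4 fell, also when adjusted over the list alone. The inhibitory SMAD Smad7 fell by -2.96 and the receptor Tgfbr2 by -4.06, and the receptor Acvr1 rose by 2.30. Of 23 ligands and antagonists 2 rose and 4 fell, also when adjusted over the list alone, with Inhba, an activin subunit, up by 4.47, and Bmp4 (-2.73) and Ltbp1 (-2.86) down. Of 18 response genes 2 rose and 2 fell, and 3 rose and 2 fell when adjusted over the list alone, with Tsc22d1 up by 2.62. These lists did not pass (camera adjusted p = 0.812, 0.606 and 0.82).

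In all, 3001 genes changed between P4 and adult control by the edgeR test, 1132 higher and 1869 lower. Of these, 2828 had no overlap between the groups' libraries, against 32.1% of all genes. Of 20 passing lists, growth cone genes (adjusted p = 0.000342), oligodendrocyte markers (0.0121) and astrocyte markers (0.0425) held with an estimated correlation. The count was 1639 in a fit of only these 2 groups, 4677 with the DESeq2 Wald test, 1852 without P4 4 and 1970 without P4 5.

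The fourth comparison set the siRNA-labelled group against adult control. Gdf10 did not differ between them (log2 fold change -0.34, adjusted p = 0.979). Ifit1 rose from 0.587 ± 0.516 to 140 ± 57.3 CPM (7.69, SE 0.72, adjusted p = 0.000474). Gpnmb (6.79), Spp1 (5.86) and Cxcl10 (5.96) also rose. The bicarbonate transporter Slc4a4 (-2.59), the lipid receptor S1pr1 (-2.59), the axonal motor Kif5a (-2.42) and Rapgef4 (-2.23) fell. Of 26 interferon response genes 4 rose, among them Ifit1, Oasl2 and Cxcl10, and 21 when adjusted over the list alone (median 2.73, camera adjusted p = 2.9e-27). Of 24 complement and MHC class I genes 4 rose (C4b, H2-D1, H2-K1 and B2m), and 13 when adjusted over the list alone (median 2.15, camera adjusted p = 7.11e-12). Of 12 astrocyte markers Slc1a2 fell, and 7 fell and 1 rose when adjusted over the list alone (median -2.06, camera adjusted p = 6.98e-08). These 3 of 21 passing lists held with an estimated correlation (adjusted p = 0.0152, 0.0224 and 0.0224). The 16 microglia markers had a median of 2.13, with 0 calls over all genes and 10 higher when adjusted over the list alone (camera adjusted p = 1.97e-08, and adjusted p = 0.179 with an estimated correlation). None of the 28 growth cone genes changed, over all genes or adjusted over the list alone, and the list had a median of -0.05 and a mean of the opposite sign, 0.19 (camera adjusted p = 0.79). In all, 21 genes changed, 15 higher and 6 lower, and 1497 had an unadjusted p under 0.05. A fit of these 2 groups alone called 0 genes in edgeR, with 897 at an unadjusted p under 0.05, and the same fit with the replicate number as a block also called 0, with 429. DESeq2 called 376 genes and limma voom 37. The count was 6 without adult control 1, and 9, 5 and 7 without siRNA-labelled libraries 1, 2 and 3, and of the 8 genes the rule named Ifit1 kept its call in every such fit.

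The fifth comparison set stroke against P4. Gdf10 was lower in stroke than in P4 (log2 fold change -5.83, SE 1.89, adjusted p = 0.0432), with 5 counts over all stroke libraries, all in stroke 5. Without stroke 5 no counts were left in stroke, and the fitted value was -9.61 (adjusted p = 0.0327). That call was lost without stroke 4 (adjusted p = 0.123) or 6 (0.135), and without P4 4 (0.11), 5 (0.135) or 6 (0.0631). It was also lost without a filter on low counts (0.0569) and with library class as a term (log2 fold change -4.99, adjusted p = 0.237). Apod, a lipid carrier of myelinating glia, rose from 2.31 ± 1.34 CPM in P4 to 5749 ± 1542 CPM in stroke (11.32, SE 0.68, adjusted p = 8.42e-08). Serpina3n (11.03), Cldn11 (10.82) and Mal (10.34) were also higher in stroke. Gjc1 (-8.81), the prostaglandin receptor Ptger3 (-8.20) and Lpl (-7.98) were lower. Of 28 growth cone genes 17 were lower in stroke, and 19 when adjusted over the list alone (median -2.25, camera adjusted p = 5.84e-10). Of 26 interferon response genes 23 were higher, and 25 when adjusted over the list alone (median 5.49, camera adjusted p = 3.36e-20). Of 24 complement and MHC class I genes 19 were higher by both counts, over all genes and adjusted over the list alone (median 4.44, camera adjusted p = 5.61e-11). All 12 oligodendrocyte markers were higher, also when adjusted over the list alone (median 8.63, camera adjusted p = 4.65e-20). Of 24 dissociation response genes 20 were higher, and 22 when adjusted over the list alone (median 2.68, camera adjusted p = 2.7e-14). These 5 of 16 passing lists held with an estimated correlation (adjusted p = 0.00354, 0.0134, 0.0161, 0.0124 and 0.0248). In all, 3359 genes changed, 1937 higher and 1422 lower. A fit of these 2 groups alone called 4789 genes, and 4567 with the replicate number as a block.

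**Figure D3:**
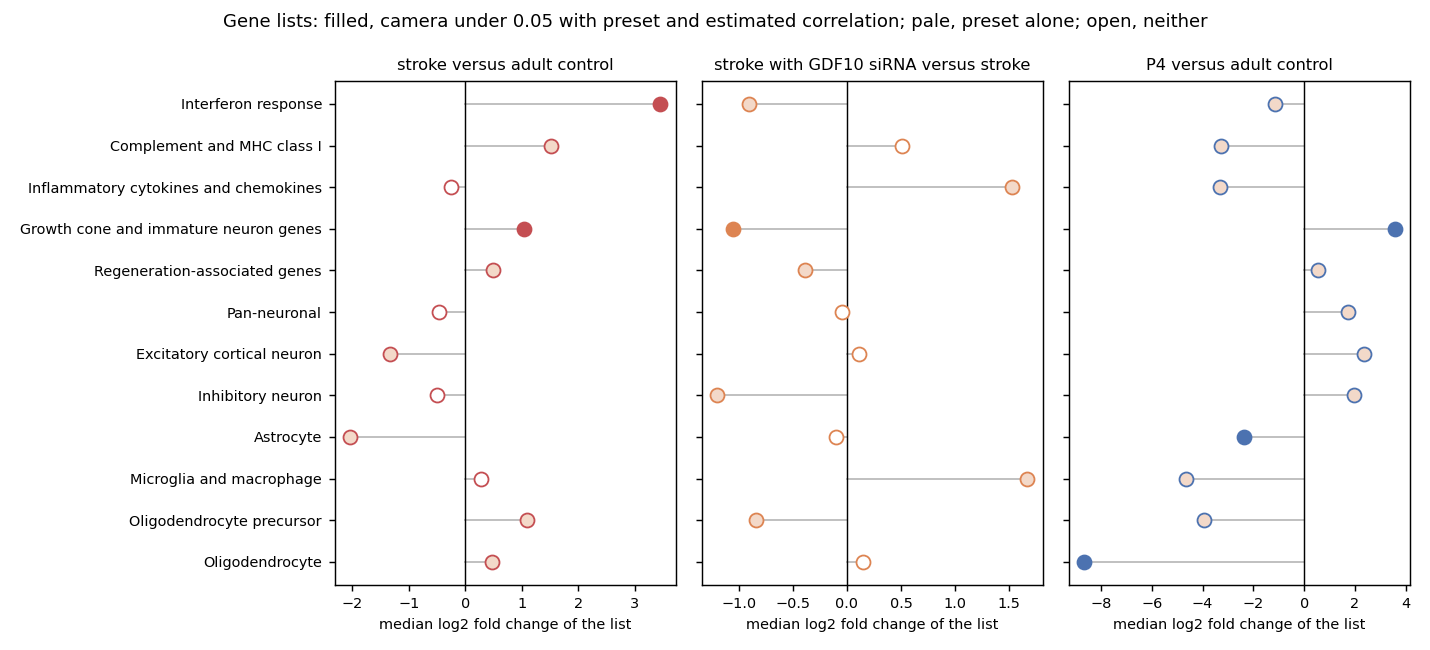
Median log2 fold change of 12 gene lists in 3 comparisons. Filled points passed the list test with a preset and with an estimated correlation, pale points with the preset one alone, and open points with neither. The growth cone list stood at 1.03 in stroke against adult control, -1.05 in the siRNA-labelled group against stroke, and 3.56 in P4 against adult control.

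The effects of stroke and of P4, each against the same adult controls, were compared over 17909 genes, which are not independent replicates. The log2 fold changes had a Pearson correlation of 0.385 and a Spearman correlation of 0.316. Unchanged groups that share the controls gave a Pearson correlation of 0.509 in simulations (0.486 to 0.522). The covariance was 1.49, against 0.669 in simulations (0.631 to 0.695). The correlation was 0.557 without adult control 1, 0.551 without adult control 2, 0.279 without adult control 3 and 0.507 without P4 6. The simulations were made for all 3 controls only, so whether the correlation lies above or below that of unchanged groups is left open. Of the 126 genes that changed in stroke, 70 (55.6%) had the opposite sign in P4, against 28.6% in simulations (24 to 32.2), and this was so for 67.8% of those higher in stroke and 28.2% of those lower. The simulations hold no shifts that many genes of a library share. The simulated ranges of this percent and of the covariance therefore do not decide how the 2 effects relate. Called genes overlapped as 16 higher in both, 22 lower in both, 33 higher in stroke and lower in P4, and 5 lower in stroke and higher in P4. Independent comparisons would give 5.5, 4.07, 9.08 and 2.47 genes, but these comparisons share their controls, so those numbers are no reference for the overlap. The 3 controls were too few to give each effect controls of its own. With library class as a term, a setting added after the data were seen, the correlation was 0.0409.

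The effect of stroke and the difference between the siRNA-labelled group and stroke share the stroke libraries with opposite sign. Their Pearson correlation over genes was -0.658 and their Spearman correlation -0.595. Simulated unchanged groups gave a Pearson correlation of -0.487 (-0.509 to -0.468). The correlation was -0.445 without siRNA-labelled library 1, -0.553 without library 2 and -0.511 without adult control 1. The simulations were made for all libraries only, so whether the correlation exceeds that of unchanged groups is left open. The covariance was -2.02, against -0.531 in simulations (-0.572 to -0.507). Of the 126 genes that changed in stroke, 115 (91.3%) had a log2 fold change of the opposite sign in the siRNA-labelled group against stroke, and simulations gave 71.8% (69.4 to 74.7). The simulations hold no shifts that many genes of a library share. The simulated ranges of this percent and of the covariance therefore do not decide whether the stroke effect was reversed. Gng4, the 1 gene called in the siRNA comparison, was also called higher in stroke than in adult control. Independent comparisons would give 0.00486 such genes, but these comparisons share the stroke libraries, so that number is no reference for the overlap.

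The deposited table of the authors called more genes than the edgeR quasi-likelihood test did. At a false discovery rate under 0.05 it called 702 genes in stroke against adult control, 37 in the siRNA-labelled group against stroke, 3592 in P4 against adult control, 195 in the siRNA-labelled group against adult control and 3858 in stroke against P4. Genes called by both were 126, 1, 2952, 21 and 3309, all with the same sign. For Gng4 the deposited log2 fold change was -2.86, with a false discovery rate of 1.05e-06.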

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

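Library class, the edgeR exact test, offsets for GC content and transcript length, and tests without Y-linked genes and Xist were chosen after seeing the data, and the other alternatives were planned. Of 4280 values of named genes under the alternatives, 3850 kept their direction and their side of the threshold, 341 no longer passed, 86 passed newly and 3 changed sign. Of 860 values of gene lists, 680 kept both, 179 no longer passed, 72 of them with an estimated correlation, and 1 changed sign. Where the counts of changed genes or the correlations moved, the cause was not tested. A fit of only the 2 groups compared has fewer samples, and an adjusted p under 0.1 is looser by construction. The median log2 fold change of all genes in stroke against adult control moved from -0.08 to -0.19 with RLE and -0.22 with upper-quartile scaling. It moved from 0.04 to 0.17 with upper-quartile scaling in the siRNA-labelled group against stroke, and from -0.04 to -0.16 and -0.20 in stroke against P4. Depth limits what can be said of Gdf10, which had 0 to 21 counts in the adult libraries. Whether replicate numbers mark pairs was left open. Between stroke and P4, residuals of libraries with the same number correlated at 0.16, 0.0136 and 0.153. Those with different numbers correlated at -0.175 to 0.151. Between the siRNA-labelled group and adult control, the values were 0.0642, -0.191 and -0.336 with the same number. With different numbers they were -0.317 to 0.481. Pseudocounts for normalized values were not run because the file holds counts, and leaving out mitochondrial and ribosomal RNA genes removed the 45S gene alone.

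In stroke against adult control, 126 genes became 1414 with the DESeq2 Wald test, 229 with limma voom, 43 with only the 2 groups compared, 289 at an adjusted p under 0.1, 41 with library class as a term, 406 with the exact test and 194 with GC and length offsets. The DESeq2 Wald test and the exact test took all 23253 genes, without the filter that left 17909, so more than the test differed. In the siRNA-labelled group against stroke, 1 gene became 0 with RLE, with upper-quartile scaling, with library class as a term and with GC and length offsets, 203 with DESeq2, 8 with voom, 2 without a filter, 88 with only the 2 groups and 13 with the exact test. In P4 against adult control, 3001 became 4677 with DESeq2 and 1639 with only the 2 groups. In the siRNA-labelled group against adult control, 21 became 13 with RLE, 376 with DESeq2, 37 with voom, 40 without a filter, 0 with only the 2 groups, with the replicate block or without it, 40 at an adjusted p under 0.1, 40 with library class as a term, 104 with the exact test and 49 with GC and length offsets. In stroke against P4, 3359 became 2049 with library class as a term. With GC and length offsets more of its genes were lower than higher (1965 higher, 2093 lower).

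Fits without 1 library gave 31 to 548 genes in stroke against adult control, 0 in all 6 fits of the siRNA-labelled group against stroke, 1852 to 3099 in P4 against adult control and 5 to 25 in the siRNA-labelled group against adult control. The correlation of the stroke and P4 effects was 0.0409 with library class as a term and 0.279 to 0.557 without 1 library, and that of the stroke and siRNA effects was -0.742 to -0.445 without 1 library. Changes of sign were seen for Gdf10 in the siRNA-labelled group against adult control (-0.88 to 0.21 without 1 library, with 0.10 without adult control 1), and for Acta2, which did not pass, in the siRNA-labelled group against stroke (-0.0245 to 4.18). The list of cytosolic ribosomal proteins in the siRNA-labelled group against stroke went from -0.262 to 0.267 with library class as a term.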

Other observations

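The tests of neuronal share, of the share of the main cell type, and of microglial and oligodendrocyte precursor markers were chosen after the results were seen, and library class was defined from the data. Axon guidance genes differed between P4 and adult control in both directions. Of 22 ephrin and Eph receptor genes 6 rose in P4 and 1 fell, also when adjusted over the list alone (median log2 fold change 1.12, camera adjusted p = 0.00963, and adjusted p = 0.197 with an estimated correlation). Efnb2, a ligand that repels growing axons, rose by 3.25 and its receptor Epha4 by 2.09. Of 25 netrin, slit and receptor genes 6 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone (median 0.81, camera adjusted p = 0.0216, and adjusted p = 0.309 with an estimated correlation). That list did not pass without P4 5 (adjusted p = 0.0546). The slit receptor Robo2 rose by 4.05 and the netrin receptor Unc5d by 2.30, and Unc5b fell by -4.45. The semaphorin receptor Plxna4 rose by 3.12, in a list that did not pass (camera adjusted p = 0.108).

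Genes of mature membranes and of neuronal activity also differed in P4. Oligodendrocyte markers took 5.87% of counts in adult control and 0.0206% in P4. For these genes and the axon guidance genes, a different mix of cells therefore cannot be told from a change within neurons. The potassium channels Kcna1 and Kcna2 fell by -5.36 and -2.42, and the synaptic protein Cplx2 rose by 2.35. Of 34 genes of mature neurons 3 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.388). Hapln2, a link protein at nodes of Ranvier, fell by -8.27. Of 22 growth-inhibitory molecules and receptors 1 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.437). Of 23 immediate early genes, switched on by neuronal activity, 4 rose and 9 fell, and 4 and 12 when adjusted over the list alone (camera adjusted p = 0.0534). Arc fell by -5.46 and Egr1 by -2.62, and Nr4a2 rose by 3.81.

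Growth cone and immature neuron genes were higher in stroke than in adult control (median 1.03) and lower in the siRNA-labelled group than in stroke (-1.05), differences that share the stroke libraries, and the siRNA-labelled group lay near adult control (-0.05). Library class was argued against as the whole cause by the medians with class as a term, 1.02 (camera adjusted p = 8.55e-07) and -0.959 (camera adjusted p = 3.84e-08), although the class effect rests on 1 adult control and 1 siRNA-labelled library. A changed share of neurons as a whole was argued against by the pan-neuronal markers outside the list, with medians of -0.735 in stroke and 0.0569 in the siRNA-labelled group. Their standard errors, 0.379 and 0.218, were taken over the markers and do not measure the spread between libraries. The pan-neuronal share ran from 0.239 to 0.696% within adult control. A changed share of a single neuronal class stays open, because inhibitory neuron markers were lower as a list in the siRNA-labelled group with the preset correlation. RNA of oligodendrocyte precursors, which a sort for neurons would remove and whose list shares 0 members with the growth cone list, may contribute: 9 of its 10 markers were lower in the siRNA-labelled group (median -0.837), while in stroke 7 of 10 were higher (median 1.08, with Gpr17 at 1439 against 328 CPM), which leaves it open there. Stroke and the siRNA-labelled treatment stay open as explanations, and neither was tested apart from this source. A batch that follows the replicate numbers also stays open, because the design cannot tell it from the group. These numbers were 1 to 3 in adult control and the siRNA-labelled group and 4 to 6 in stroke.

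Microglia and macrophage genes were higher in the siRNA-labelled group than in stroke as a list (median 1.67, camera adjusted p = 4.3e-08), but not with an estimated correlation (adjusted p = 0.31), and none of the 16 passed over all genes. The test of the share of the main cell type asked whether oligodendrocyte and astrocyte markers rose along with the microglia markers. Their medians of 0.152 and -0.103 argue against a rise of all glial markers alike. Oligodendrocyte markers took a larger share of counts than pan-neuronal markers in these libraries. A lower share of oligodendrocytes would not raise their own markers, so the rule of this test cannot decide on that. Library class was argued against as the whole cause by the median of 1.73 with class as a term (camera adjusted p = 2.06e-10 with the preset correlation). The class effect rests on 1 adult control and 1 siRNA-labelled library with a high 45S share. More microglial or macrophage RNA, from cells that a sort for neurons would remove, stays open: 16 of the 16 markers had a higher mean, but these genes are the pattern itself and do not test it. An effect of the treatment, whose nature the sources leave in doubt, and a different carry-over in the sort also stay open. So does a batch that follows the replicate numbers, which the design cannot tell from the group.

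The deposited table called 702 genes in stroke against adult control, the quasi-likelihood test 126 and the edgeR exact test 406. The exact test was run on all 23253 genes, and the quasi-likelihood test without a filter on low counts called 158. Among the 576 genes called in the deposited table alone, 22% had overlapping libraries between the groups, against 0% of the 126. The quasi-likelihood test selects genes whose groups are separate, so this gap alone decides nothing. A single library held a median of 56.6% of the summed CPM in the 576 genes and 37.3% in the 126, and adult control 3 was the highest library in 60.9% and 19%. Among genes lower in stroke, a split chosen after the results were seen, these values were 78.2% and 89.1% for 394 genes of the deposited table alone and 39.7% and 61.5% for 39 genes of both, and a biological cause was not tested.

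The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 126 genes in stroke against adult control, 1 in the siRNA-labelled group against stroke, 3001 in P4 against adult control, 21 in the siRNA-labelled group against adult control and 3359 in stroke against P4, and the highest of the other splits gave 0 in each.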
